A study of Mus musculus with 21 samples.

How the data were processed

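Left ventricular myocardium of C57BL/6J mice was profiled by RNA sequencing in 21 libraries, 1 per animal, each animal carrying its own ear tag. Sham-operated mice gave 5 libraries, mice with transverse aortic constriction (TAC, which narrows the aorta and overloads the left ventricle) gave 5, mice with TAC and a PDE5A inhibitor gave 5, and mice with TAC and a PDE9A inhibitor gave 6. Per the labels' protocols the inhibitors were given for 4 weeks, starting 1 week after surgery, RNA was extracted from flash-frozen myocardium, and stranded total RNA libraries were made from 500 ng. The doses, and the vehicle or lack of one in the untreated groups, are not given in the sources used here.

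The values are RSEM expected counts per gene symbol, deposited by the authors as 1 table of 24054 rows with a column per library. The deposited expected counts were not scaled between libraries, and 19% of the values had decimals. CASAVA 1.8.4, HISAT2 2.0.5, RSEM 1.3.0, DESeq2 1.18.1 and the genome build mm10 are named in the submitters' processing notes, with no role or order. The annotation behind the symbols is not given in the sources used here. A set of 27 rows carried a date in place of a symbol, the usual damage done by a spreadsheet, and were named nowhere in the text. No gene of the mitochondrial genome was in the table, so the mitochondrial share of the counts was not analysed here. For coordinates, 22683 symbols were matched to exactly 1 gene of GENCODE mouse release M21 (GRCm38, the assembly that mm10 names). A gene's coordinates span all of its annotated transcripts, exons and introns together. Every gene located in the text is annotated as protein-coding.

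Expected counts were rounded to whole numbers. Genes with low counts were removed with filterByExpr by group, which left 14135. Libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group and no covariate was fitted to all libraries with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, so that all comparisons share 1 estimate of the spread. P-values were adjusted by Benjamini and Hochberg over the genes tested in each comparison, and a gene was called at an adjusted p under 0.05. "Rose" and "fell" are used of called genes. Standard errors are of the log2 fold change, and changes given without a unit are on the log2 scale. Levels are TMM-scaled counts per M (CPM), given as mean ± SD over the animals of a group. The comparisons were TAC against sham, each inhibitor group against TAC, the 2 inhibitor groups against each other, and each inhibitor group against sham.

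Gene lists for the tissue and treatment, and marker lists for cell types that left ventricle or its dissection could hold, were fixed before the data were examined, as were the tests, the named genes' rule and the first alternatives. Of 42 lists, 37 had at least 3 tested members. The lists for the mitochondrial genome, white adipocytes, mesothelium and epicardium, lung and thymus had fewer and were not tested. Lists were tested with camera (limma 3.58.1, on voom values, preset correlation 0.01), adjusted over the 37 lists of a comparison. Camera with an estimated correlation and fry (which asks whether a list's genes move one way on balance, without comparing them with other genes) were run beside it. A score, the mean log2 CPM of a list's members with a prior count of 2, was computed per library. Scores were compared by two-sided exact permutation tests, whose smallest p is 0.00794 for 5 against 5 libraries and 0.00216 for 6 against 5. Adjusted over 37 lists, 1 list alone at the smallest p cannot pass.

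Genes were named by this rule. From each of the first 4 comparisons came the 8 largest rises and 8 largest falls among called genes without overlap between the groups in CPM and with a mean of at least 1 CPM in the higher group, leaving out predicted-gene symbols. From each pathway list came up to 4 called members with the lowest adjusted p. Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Postn, Pde5a, Pde9a, Prkg1 and Npr1 were taken in each of these 4 comparisons. Where the first part gave no gene, the 5 with the lowest p in each direction were taken. Genes called in TAC against sham and called the other way against TAC were named too. Genes named outside this rule are said to be so, except in the accounts of library totals and principal components. Some genes that the rule names are not reported here.

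Comparisons that share the TAC libraries also share their chance values, with opposite sign for TAC against sham and an inhibitor against TAC, and with the same sign for the 2 inhibitors against TAC. The share of TAC genes with the opposite sign under an inhibitor, and the correlation of the inhibitors' fold changes, were therefore set beside 24 simulated data sets in which the inhibitor groups had the TAC means and genes varied independently. They were also set beside 100 data sets made by resampling the residuals of whole libraries, which keeps genes correlated (tested with limma on log2 CPM). In 20 further fits the TAC libraries were split, so that the 2 comparisons shared none. The other alternatives were RLE size factors, no filter on low counts, a filter of 1 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, a model of only the groups compared, a replicate block, the ear tag series (the first digit of the tag, 3 series) as a term, and leaving out each library in turn. Added after seeing the data were the resampling, the jackknife standard errors, fits without PDE9A inhibitor libraries 1 and 4, fits with the share of Rn45s counts (an unspliced ribosomal RNA gene, a sign of ribosomal RNA carried into the library) as a covariate, and B cell scores without each marker and with counts thinned to the lowest library total.

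The tests were tried on simulated data with 200 of 14135 genes changed. Genes varied independently around the TAC means, with the same spread per gene in all groups. In the simulated TAC against sham comparison edgeR recovered 58.0% of genes changed 1.5-fold, 89.2% of those changed 2-fold and 97.0% of those changed 4-fold, with 6 calls among unchanged genes. In the simulated PDE5A inhibitor against TAC comparison the shares were 56.5%, 74.6% and 95.8%, with 7 false calls. In the simulated PDE9A inhibitor against TAC comparison they were 60.7%, 78.6% and 97.1%, with 2 false calls. In the simulated comparison of the inhibitors they were 56.6%, 79.7% and 97.1%, with 8 false calls. DESeq2 made 24, 20, 23 and 14 false calls in these comparisons. Shifts shared by many genes of a library and unequal spread between groups were not simulated, so these rates need not hold for the real data. Total counts ran from 22.7 to 41.0 M per library, and a count of 3, taken as the floor, is worth 0.0781 to 0.135 CPM. Intervals and floors of this kind cover counting error only, since the libraries carry no molecular identifiers. No library was left out.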

Results

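Gene expression was measured in the left ventricle of 21 mice by sequencing of total RNA. Of these, 5 had sham surgery, 5 had TAC, 5 had TAC with the PDE5A inhibitor sildenafil, and 6 had TAC with the PDE9A inhibitor PF-04449613. PDE5A and PDE9A are phosphodiesterases that break down cyclic GMP, the second messenger made by the natriuretic peptide receptors and by the nitric oxide-sensitive guanylate cyclase. The series title places both drugs in a pressure-overload model of heart failure, and the question is how each inhibitor alters myocardial expression under overload. Total counts per library averaged 30.3 ± 6.08 M in sham, 28.0 ± 3.12 M in TAC, 34.1 ± 4.13 M in the PDE5A inhibitor group and 27.5 ± 3.46 M in the PDE9A inhibitor group (SD). Titin (Ttn) was the most abundant gene in every library and took 8.08 to 10.5% of the counts. Rn45s took 0.192 to 0.278% of the counts in 19 libraries, 0.326% in PDE9A inhibitor library 1 and 0.416% in PDE9A inhibitor library 4. No pair of libraries within a group was alike within counting noise.

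The first principal component held 42.3% of the variance and carried Comp, Fmod, Ltbp2 and Myh7 at its high end and Ccl11 at its low end. Sham libraries scored -36.2 ± 7.45, TAC libraries 22.4 ± 24.3, PDE5A inhibitor libraries 13.1 ± 17.5 and PDE9A inhibitor libraries 0.551 ± 28.0 (SD, n = 5, 5, 5 and 6). The PDE9A inhibitor group thus covered nearly the whole axis, from -37.0 in library 6, within the sham range, to 36.9 in library 4. The second component held 10.1% of the variance and set apart PDE9A inhibitor libraries 1 (39.0) and 4 (35.3), the libraries with the highest Rn45s shares.

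**Figure D1:**
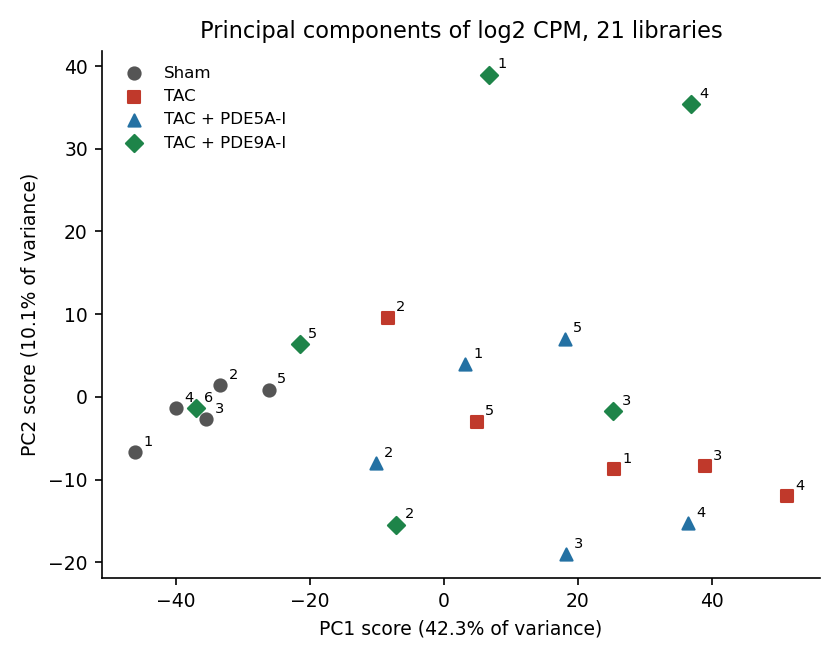
Scores of the 21 libraries on the first and second principal components of log2 CPM, with the replicate number beside each point and a symbol per group. Sham libraries lie between -46.1 and -26.1 on the first component, and PDE9A inhibitor libraries 1 and 4 stand at 39.0 and 35.3 on the second.

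TAC against sham asks what pressure overload alone did. Genes of the fetal and hypertrophic programme rose together: 12 of 13 tested members of that list rose, and the same 12 counted when adjusted over the list alone. Myh7 (beta myosin heavy chain, the slow isoform; ENSMUSG00000053093.16, chromosome 14, 54970684 to 54994626) rose from 244 ± 52.4 CPM in sham to 5745 ± 2537 CPM in TAC (SD, n = 5 each; log2 fold change 4.56, SE 0.86, adjusted p = 0.00312). Nppa, which encodes atrial natriuretic peptide (ENSMUSG00000041616.9, chromosome 4, 148000722 to 148002079), rose from 172 ± 92.5 to 2717 ± 1888 CPM (log2 fold change 3.98, SE 0.81, adjusted p = 0.00402). Nppb (brain natriuretic peptide), skeletal alpha-actin Acta1 and the stretch-responsive Ankrd1 and Ankrd23 rose with log2 fold changes of 2.16 (SE 0.39), 2.92 (SE 0.63), 2.02 (SE 0.31) and 1.17 (SE 0.20). The list passed camera (adjusted p = 6.16e-09) but not camera with an estimated correlation (adjusted p = 0.470 with an estimated correlation). Its fry test (adjusted p = 0.00223) and its score (difference 1.93, exact permutation p = 0.00794, adjusted p = 0.0173, no overlap between the 5 and 5 libraries) passed. In the sarcomere and Z-disc list 3 of 19 members rose and 5 fell, and the list as a whole did not pass (adjusted p = 0.224). Its members went opposite ways: Myh6 (alpha myosin heavy chain, the fast isoform of the adult mouse ventricle) fell from 45267 ± 2936 to 27455 ± 8295 CPM (log2 fold change -0.72, SE 0.19, adjusted p = 0.0111). Tnni3 (cardiac troponin I) and Tcap (a Z-disc protein) fell with log2 fold changes of -0.69 (SE 0.16) and -0.77 (SE 0.19), and Myom2 (an M-band protein) rose by 0.57 (SE 0.14).

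Extracellular matrix genes rose as a block. Of the 36 members tested 35 rose (36 adjusted over the list alone), with a median log2 fold change of 2.22. Comp (cartilage oligomeric matrix protein; ENSMUSG00000031849.9, chromosome 8, 70373558 to 70382066) rose from 5.85 ± 4.94 to 152 ± 85.5 CPM (log2 fold change 4.67, SE 0.93, adjusted p = 0.00375). Postn (periostin; ENSMUSG00000027750.16, chromosome 3, 54361109 to 54391037) rose from 93.4 ± 15.6 to 1345 ± 1103 CPM (log2 fold change 3.85, SE 0.72, adjusted p = 0.00294). The matrix genes Thbs4, Cilp, Col12a1 and Spp1 rose with log2 fold changes of 4.51 (SE 0.73), 3.97 (SE 0.64), 4.53 (SE 0.75) and 3.86 (SE 0.70). The type I collagen gene Col1a1 rose by 1.90 (SE 0.56), a call that ended with the ear tag series as a term and without sham library 1, TAC library 3 or TAC library 4. In the TGF-beta list 10 of 22 members rose and 1 fell (14 and 1 adjusted over the list alone), among them the latent binding protein Ltbp2 (4.53 (SE 0.86)), the ligand Tgfb2 (1.99 (SE 0.40)), the TGF-beta-induced matrix protein Tgfbi (0.70 (SE 0.16)) and the stress cytokine Gdf15 (4.25 (SE 0.99)). Camera gave adjusted p = 7.58e-16 for the matrix list and 0.000985 for the TGF-beta list. With an estimated correlation they gave adjusted p = 0.470 and 0.596. Beside these lists, all 10 markers of activated fibroblasts rose (7 of them also in the matrix list), 8 of 12 general fibroblast markers rose and 1 fell, and 6 of 12 cardiomyocyte markers fell (camera adjusted p = 8.44e-08, 0.000985 and 0.000371; adjusted p = 0.470 with an estimated correlation for each). Most of these fibroblast markers thus made up more of the RNA in the TAC libraries. Whether the tissue held more fibroblasts was not tested.

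Genes of mitochondrial energy metabolism fell. In the nuclear-encoded oxidative phosphorylation list 32 of 33 members fell (33 adjusted over the list alone; median -0.44). In fatty acid uptake and oxidation 24 of 28 fell (27 adjusted over the list alone; median -0.59), and in the tricarboxylic acid cycle list, with pyruvate dehydrogenase, 13 of 16 (16 adjusted over the list alone; median -0.42). Etfb, the beta subunit of the electron transfer flavoprotein, fell from 499 ± 29.3 to 268 ± 74.2 CPM (log2 fold change -0.90, SE 0.18, adjusted p = 0.00402). The fatty acid transporter Cd36, the enoyl-CoA isomerase Ech1 and the thioesterase Acot2 fell with log2 fold changes of -0.49 (SE 0.12), -0.98 (SE 0.24) and -0.92 (SE 0.23). Respiratory chain members fell too: Cox6c -0.50 (SE 0.12), Cox7b -0.49 (SE 0.12), cytochrome c (Cycs) -0.51 (SE 0.12) and the succinate dehydrogenase subunit Sdha -0.60 (SE 0.15). Of the cycle's enzymes Suclg1 and citrate synthase (Cs) fell with log2 fold changes of -0.58 (SE 0.14) and -0.48 (SE 0.13). Of 15 regulators of the PGC-1, PPAR and ERR group 6 fell (13 adjusted over the list alone), including the coactivators Ppargc1a (-0.61 (SE 0.16)) and Ppargc1b (-0.43 (SE 0.10)) and the nuclear receptors Ppara (-0.57 (SE 0.15)) and Rxra (-0.39 (SE 0.10)). Camera adjusted p-values were 3.57e-13, 3.07e-11, 8.4e-07 and 2.16e-05 in that order, against adjusted p = 0.470, 0.470, 0.477 and 0.470 with an estimated correlation. Cardiomyocyte markers, which lie in the same cells, fell in 6 of 12 cases as given above, with a median of -0.37. Glycolysis and glucose transport did not pass as a list (1 of 18 rose, 3 fell, adjusted p = 0.994). The phosphofructokinase Pfkp rose by 1.12 (SE 0.27). The insulin-responsive transporter Slc2a4 fell with a log2 fold change of -0.49 (SE 0.15), a call that ended without sham library 1 or 4 or TAC library 3 or 4.

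Calcium handling and ion channel genes fell: 13 of 22 members were lower and none was called higher (16 adjusted over the list alone; camera adjusted p = 1.92e-06; adjusted p = 0.470 with an estimated correlation). Atp2a2, the sarcoplasmic reticulum calcium pump SERCA2 (ENSMUSG00000029467.15, chromosome 5, 122453513 to 122502225), fell from 19702 ± 1320.2 to 10848 ± 2932 CPM (log2 fold change -0.86, SE 0.18, adjusted p = 0.00405). The calcium release channel Ryr2 and the potassium channels Kcnj2 and Kcnk3 fell with log2 fold changes of -0.72 (SE 0.15), -0.86 (SE 0.18) and -0.64 (SE 0.14). In the cyclic GMP pathway 2 of 27 members rose and 5 fell (3 and 6 adjusted over the list alone), and the list did not pass (adjusted p = 0.994). Rgs2, a regulator of G protein signalling that is a target of cyclic GMP-dependent kinase, fell from 42.7 ± 5.55 to 14.8 ± 5.62 CPM (log2 fold change -1.53, SE 0.28, adjusted p = 0.00262). The proteases that process natriuretic peptides, Corin and Furin, fell with log2 fold changes of -0.67 (SE 0.11) and -0.46 (SE 0.09). The kinase gene Prkg1 rose (log2 fold change 0.35, SE 0.08, adjusted p = 0.00655). The drug targets themselves were not called: Pde5a (ENSMUSG00000053965.10, chromosome 3, 122728947 to 122859374) stood at 10.7 ± 1.64 CPM against 10.5 ± 1.24 (log2 fold change 0.03, SE 0.11, adjusted p = 0.848). Pde9a (ENSMUSG00000041119.12, chromosome 17, 31386210 to 31476310) stood at 3.61 ± 0.926 CPM against 2.63 ± 0.498 (log2 fold change 0.46, SE 0.27, adjusted p = 0.205). The natriuretic peptide receptor gene Npr1 gave log2 fold change -0.04, SE 0.11, adjusted p = 0.807. Rcan1, a calcineurin target and inhibitor, rose by 1.64 (SE 0.41), while the calcineurin, NFAT and MEF2 list did not pass (1 of 15 rose, 3 fell, adjusted p = 0.281).

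Interferon-stimulated genes rose in 8 of 20 cases (8 adjusted over the list alone; camera adjusted p = 0.000229; adjusted p = 0.618 with an estimated correlation; fry adjusted p = 0.0923), with Ifit2 at 0.77 (SE 0.18) and Oasl2 at 0.81 (SE 0.22). The 5 tested B cell markers all rose, with log2 fold changes of 1.05 (SE 0.20) for Cd79b and 1.08 (SE 0.25) for Cd79a, the chains of the B cell receptor's signalling part (camera adjusted p = 0.000717, and adjusted p = 0.470 with an estimated correlation). B cell markers are not a pathway list, so these folds are given here outside the naming rule. Unfolded protein response genes fell in 8 of 20 cases (1 higher and 9 lower adjusted over the list alone), led by the endoplasmic reticulum chaperones Hspa5 (-0.60 (SE 0.11)) and Hsp90b1 (-0.39 (SE 0.07)), with camera adjusted p = 0.00778 and adjusted p = 0.470 with an estimated correlation. Inflammation and chemokine genes did not pass as a list (5 of 27 rose, 2 fell, adjusted p = 0.161). Its members went both ways: the lectin Lgals3 rose by 2.46 (SE 0.62), a call that ended without TAC library 4. The chemokine Cx3cl1 rose (23.9 ± 10.6 CPM against 10.5 ± 1.73), and the chemokines Ccl6 and Cxcl12 fell with log2 fold changes of -1.07 (SE 0.21) and -0.40 (SE 0.11). Nox4, a hydrogen peroxide-producing NADPH oxidase (ENSMUSG00000030562.17, chromosome 7, 87246096 to 87398710), rose from 2.56 ± 0.698 to 20.7 ± 3.30 CPM (log2 fold change 3.00, SE 0.47, adjusted p = 0.00202). In its list 5 of 20 members rose and 3 fell (adjusted p = 0.878). The peroxidase gene Gpx3 rose by 0.99 (SE 0.23) and the peroxiredoxin gene Prdx1 fell (log2 fold change -0.31 (SE 0.08)). In the circadian list 1 of 18 members rose and 4 fell (adjusted p = 0.291), among them the repressor Cry2 (log2 fold change -0.58 (SE 0.16)). Cell cycle (2 rose and 1 fell of 27, adjusted p = 0.291), immediate early (none called of 19, adjusted p = 0.130) and microRNA biogenesis genes (1 fell of 16, adjusted p = 0.490) did not pass as lists.

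The largest rises outside these lists were in genes with low sham levels. Tnmd (tenomodulin) stood at 3.62 ± 1.63 CPM against 0.128 ± 0.146 CPM. Chodl (chondrolectin) stood at 1.29 ± 0.937 CPM against 0.0181 ± 0.0254, Gpr123 at 1.67 ± 1.12 CPM against 0.0635 ± 0.0579 and Ptx4 at 1.29 ± 0.697 CPM against 0.0462 ± 0.0326. The sham means of these 3 genes lie under the level of 3 counts, so no fold is given. Among the largest falls were Ccl11, the chemokine eotaxin (0.196 ± 0.213 CPM against 2.64 ± 0.676, log2 fold change -3.70 (SE 0.75)) and Rp1 (0.132 ± 0.116 CPM against 1.02 ± 0.566, in TAC at about the level of 3 counts, so no fold is given). Ccl11 stood at or under 3 counts in TAC libraries 1, 2 and 4 (0, 0.1347 and 0.09855 CPM), so the size of its fold is uncertain. Among the other falls were the water channel Aqp4 (-2.72 (SE 0.56)), the kinetochore gene Cenpf (-2.61 (SE 0.52)), the tolloid-like protease Tll2 (-2.57 (SE 0.64)), Retnla (-2.50 (SE 0.62)) and Ankrd63 (-2.45 (SE 0.47)).

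Over all genes tested edgeR called 3558 of 14135, 1718 higher and 1840 lower in TAC, of which 511 and 201 changed more than 2-fold. At an unadjusted p under 0.05 there were 5592 genes against 707 expected by chance. Of all 14135 genes, 2335 had no overlap between the groups, where chance gives a share of 0.00794. With the ear tag series as a term 2681 genes were called. The count fell to 2019 without TAC library 3 and to 1781 without TAC library 4, of which 1997 and 1766 were among the genes called with all libraries.

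**Figure D2:**
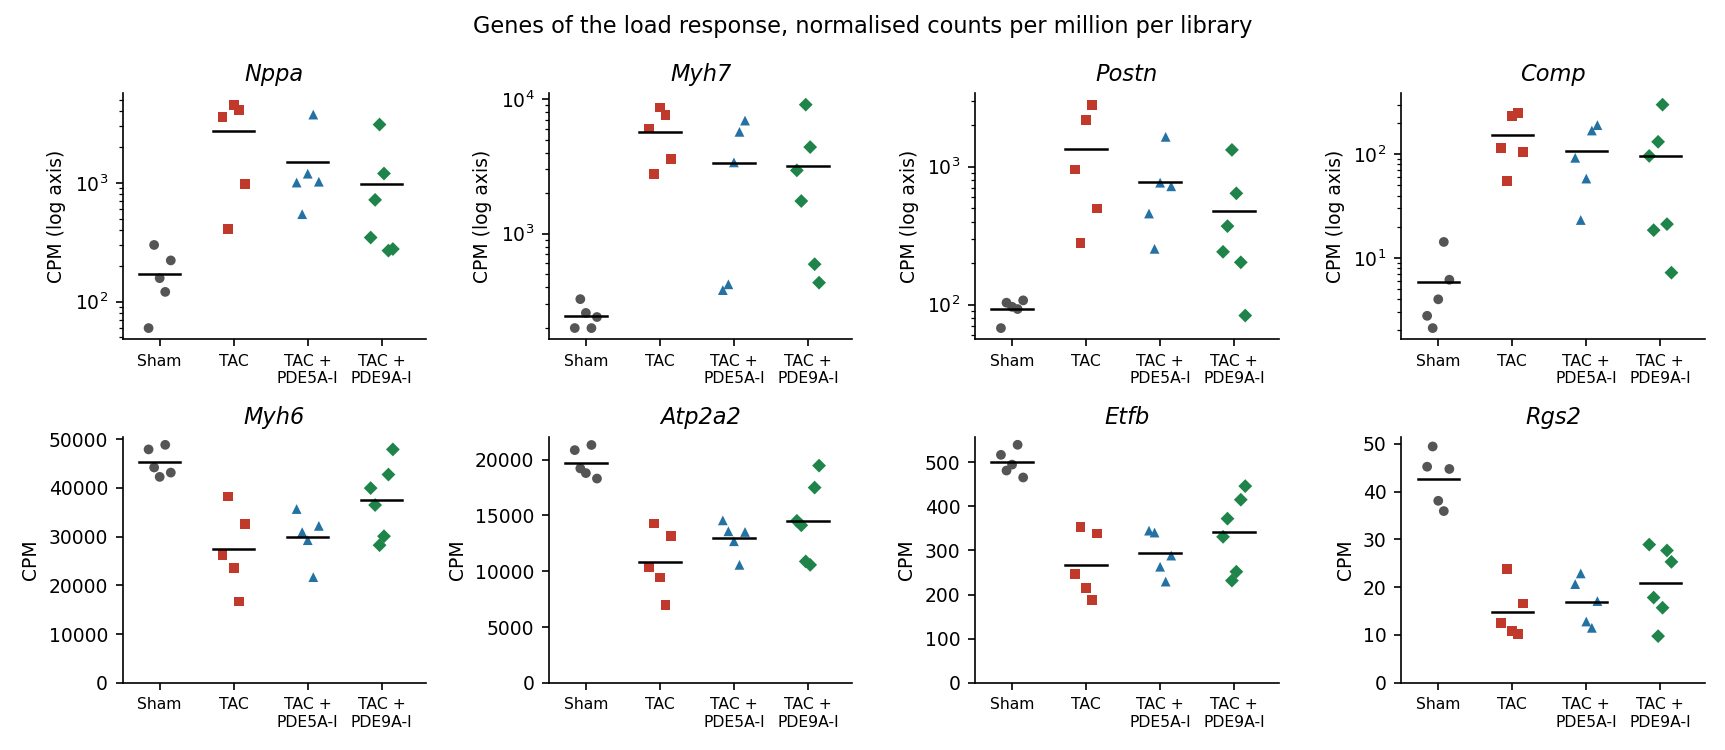
CPM per library for 8 genes in the 4 groups, on log axes for Nppa, Myh7, Postn and Comp and on linear axes from 0 for Myh6, Atp2a2, Etfb and Rgs2; the horizontal line is the group mean. TAC libraries lie above all sham libraries for Nppa, Myh7, Postn and Comp and below them for Myh6, Atp2a2, Etfb and Rgs2, and the libraries of the inhibitor groups spread widely.

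PDE5A inhibitor against TAC asks what sildenafil altered under overload. The number of genes that rose was 2, of which 1 is given here, and none fell. St8sia1, a sialyltransferase of ganglioside synthesis (ENSMUSG00000030283.7, chromosome 6, 142821545 to 142964452), rose from 0.672 ± 0.318 CPM in TAC to 3.17 ± 1.52 CPM with the inhibitor (SD, n = 5 each; log2 fold change 2.22, SE 0.36, adjusted p = 0.0337). The genes of the load response were not called: Nppa stood at 1502 ± 1278 CPM against 2717 ± 1888 (log2 fold change -0.86, SE 0.72, adjusted p = 0.962). Postn stood at -0.81 (SE 0.65), Myh7 at -0.77 (SE 0.75), Acta1 at 0.42 (SE 0.59), Col1a1 at -0.27 (SE 0.54), Atp2a2 at 0.26 (SE 0.18), Myh6 at 0.13 (SE 0.19) and Nppb at -0.01 (SE 0.37) on the log2 scale, all with adjusted p of 0.962 or more. Pde5a (0.07 (SE 0.11)), Pde9a (-0.09 (SE 0.26)), Prkg1 (-0.06 (SE 0.08)) and Npr1 (0.12 (SE 0.11)) were not called either. Members of lists changed by TAC can lean to the sham side with no drug effect, since the TAC libraries also enter TAC against sham, and no such value was simulated per list. By list, 28 of 28 fatty acid genes were higher (median 0.15, camera adjusted p = 3.98e-05), as were 14 of 15 PGC-1, PPAR and ERR regulators (adjusted p = 0.00128; adjusted p = 0.837 and 0.837 with an estimated correlation). Lower were 34 of 36 matrix genes (median -0.34, adjusted p = 0.00649) and 10 of 10 activated fibroblast markers (adjusted p = 0.0175; adjusted p = 0.930 and 0.837 with an estimated correlation). No member was called. Cell cycle genes (23 of 27 higher, adjusted p = 3.98e-05) and erythroid markers (8 of 8 higher, median 0.57, adjusted p = 5.69e-05), which mark blood in the sample, were also higher (adjusted p = 0.837 and 0.837 with an estimated correlation). The other lists passing camera were endothelial markers (10 of 12 higher, adjusted p = 0.00588) and the tricarboxylic acid cycle (15 of 16 higher, 0.0351; adjusted p = 0.837 and 0.930 with an estimated correlation). On the lower side were inflammation (22 of 27, 0.00588), immediate early genes (18 of 19, 0.0197) and TGF-beta signalling (18 of 22, 0.0234; adjusted p = 0.837, 0.930 and 0.837 with an estimated correlation). Adjusted over the list alone, 1 PGC-1, PPAR and ERR regulator was higher and 1 endocardial marker lower. Camera called 11 of 37 lists, 6 upward and 5 downward. None passed with an estimated correlation, with fry or by score. At an unadjusted p under 0.05 there were 731 genes against 707 expected by chance, and DESeq2 called 8. Only leaving out PDE5A inhibitor library 1 kept both calls. Without TAC library 1 or PDE5A inhibitor library 2 the count was 1. Without TAC library 2, 3, 4 or 5 or PDE5A inhibitor library 3, 4 or 5 it was 0, while with the ear tag series as a term it was 1.

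PDE9A inhibitor against TAC asks the same of PF-04449613. B cell markers were lower: Cd79a, the alpha chain of the B cell receptor's signalling part (ENSMUSG00000003379.7, chromosome 7, 24897381 to 24902197), fell from 0.647 ± 0.140 CPM in TAC (n = 5) to 0.209 ± 0.0410 CPM with the inhibitor (n = 6, SD; log2 fold change -1.62, SE 0.25, adjusted p = 0.0286). It was the only gene called in this comparison. Its partner Cd79b (ENSMUSG00000040592.11, chromosome 11, 106311341 to 106314762) stood at 0.596 ± 0.121 CPM against 1.34 ± 0.327 and did not pass (log2 fold change -1.15, SE 0.20, adjusted p = 0.0628). All 5 B cell markers tested were lower (median -1.32; 4 fell adjusted over the list alone), with camera adjusted p = 9.06e-08, adjusted p = 0.0544 with an estimated correlation, and fry adjusted p = 0.000291. The difference in B cell score, inhibitor minus TAC, was -1.14, without overlap between the 6 and 5 libraries. Its exact permutation p of 0.00216 is the smallest this design can give. Adjusted over 37 lists it was 0.0801, so it did not pass, which 1 list alone cannot do in this design. These markers are rare transcripts, with 31 to 84 counts summed over the 5 markers per library in the inhibitor group and 103 to 180 in TAC. Among the genes with the lowest p that did not pass, Ppargc1b (PGC-1 beta) stood at 33.7 ± 4.50 CPM against 24.7 ± 1.35 (log2 fold change 0.45, SE 0.09, adjusted p = 0.254). Spen stood at 0.63 (SE 0.13), Zfp592 at 0.39 (SE 0.09), Rbbp6 at 0.34 (SE 0.07) and Sh2b1 at 0.33 (SE 0.07). On the lower side were Stmn2 (-0.62 (SE 0.13)), Klhl6 (-0.61 (SE 0.15)), Nifk (-0.28 (SE 0.07)) and Utp3 (-0.20 (SE 0.05)).

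No load-response gene was called in that comparison either. Nppa stood at 982 ± 1093 CPM against 2717 ± 1888 (log2 fold change -1.47, SE 0.69, adjusted p = 0.338). Postn stood at -1.50 (SE 0.62), Myh7 at -0.84 (SE 0.71), Nppb at -0.81 (SE 0.35), Acta1 at -0.35 (SE 0.56), Col1a1 at -0.17 (SE 0.52), Myh6 at 0.45 (SE 0.18) and Atp2a2 at 0.42 (SE 0.17) on the log2 scale, with adjusted p from 0.282 for Myh6 to 0.908 for Col1a1. Pde9a itself gave log2 fold change -0.57, SE 0.26, adjusted p = 0.320, Pde5a 0.02 (SE 0.10), Prkg1 0.02 (SE 0.08) and Npr1 0.01 (SE 0.10). The TAC libraries enter TAC against sham as well, so this lean arises here too with no drug effect. By list, 13 of 13 hypertrophy genes were lower (median -0.76, camera adjusted p = 3.76e-06), and 36 of 36 matrix genes were lower (median -0.66, adjusted p = 1.11e-09). Higher were 33 of 33 oxidative phosphorylation genes (median 0.11, adjusted p = 0.00124), 26 of 28 fatty acid genes (adjusted p = 8.94e-05) and 19 of 22 calcium handling and ion channel genes (median 0.26, adjusted p = 8.61e-05). No member was called. With an estimated correlation these lists gave adjusted p = 0.610, 0.610, 0.730, 0.717 and 0.610. Activated fibroblast markers were lower (10 of 10, adjusted p = 2.41e-05) and cardiomyocyte markers higher (11 of 12, adjusted p = 0.00170), as were erythroid markers (8 of 8, adjusted p = 0.00272), each with adjusted p = 0.610 with an estimated correlation. Also higher were PGC-1, PPAR and ERR regulators (14 of 15, 8.94e-05), the tricarboxylic acid cycle (16 of 16, 0.00238) and sarcomere genes (15 of 19, 0.0310; adjusted p = 0.610, 0.717 and 0.717 with an estimated correlation). Adjusted over the list alone, 2 PGC-1, PPAR and ERR regulators, 5 cyclic GMP pathway genes, 4 microRNA biogenesis genes and 1 T and NK cell marker were higher, and of calcineurin, NFAT and MEF2 genes 2 were higher and 1 lower. Camera called 12 of 37 lists, 8 upward and 4 downward. None held with an estimated correlation, and B cells alone passed fry. Without PDE9A inhibitor libraries 1 and 4 further lists passed camera downward: inflammation (adjusted p = 0.00108, against 0.281 with all libraries), TGF-beta signalling (0.00772, against 0.438), macrophage markers (0.00772, against 0.247) and interferon-stimulated genes (0.000316, against 0.628 upward). With the Rn45s share as a covariate inflammation (0.0270) and macrophage markers (0.00869) passed too, but TGF-beta signalling (0.0749) and interferon-stimulated genes (0.397) did not. Libraries 1 and 4 were chosen after the data were seen and had the group's highest inflammation, macrophage and interferon scores. Leaving them out thus lowers these lists whatever the drug did. For TGF-beta signalling they scored 4.891 and 5.353 (others of the group 4.422 to 5.218), so the same can hold there. The Rn45s share was highest in the same libraries, so that covariate is no separate check. Camera with an estimated correlation was not run on these fits. At an unadjusted p under 0.05 there were 2061 genes against 707 expected by chance. The 707 is a mean. Genes vary together across libraries, so the number by chance alone can lie far from it, and it was not counted in regroupings. DESeq2 called 33 genes, Cd79a among them. Without PDE9A inhibitor library 2 edgeR called 46 genes including Cd79a. Without any other of the 11 libraries, with the ear tag series as a term and without PDE9A inhibitor libraries 1 and 4 it called 0.

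**Figure D3:**
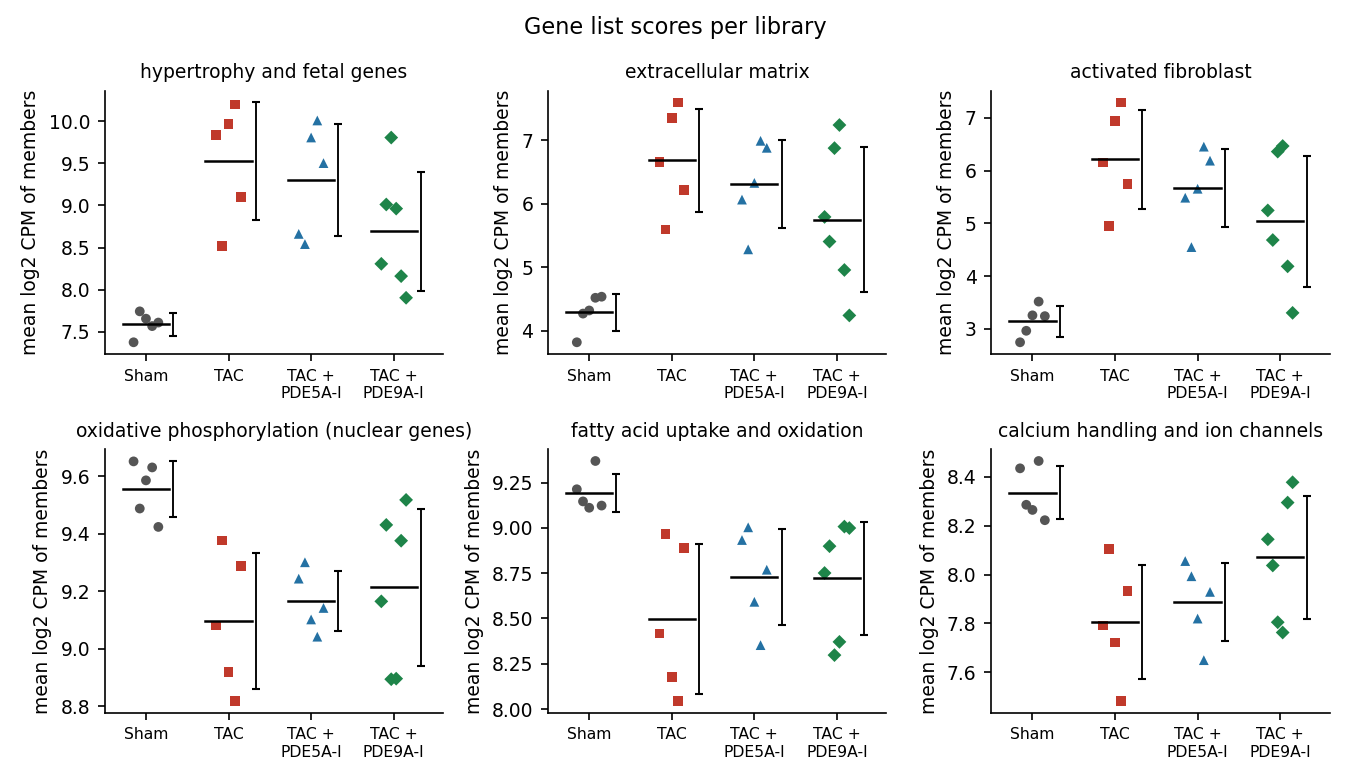
Scores (mean log2 CPM of a list's tested members) per library for 6 gene lists, with a symbol per group, the group mean as a horizontal line and its SD as the bar beside it. TAC libraries lie apart from sham libraries in all 6 panels, and PDE9A inhibitor libraries reach into the sham range for the matrix, activated fibroblast, oxidative phosphorylation and calcium handling lists.

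The inhibitors were compared directly, PDE5A inhibitor against PDE9A inhibitor. Their targets are related enzymes, but their doses are not given in the sources used here, so the readouts cannot be matched by dose. The treatment time was the same. Cd79b was 1.60 ± 0.288 CPM with the PDE5A inhibitor (n = 5) and 0.596 ± 0.121 with the PDE9A inhibitor (n = 6), the only gene called (log2 fold change 1.41, SE 0.19, adjusted p = 0.00591). All 5 B cell markers were higher with the PDE5A inhibitor and all 5 passed adjusted over the list alone. The list passed camera (adjusted p = 1.37e-09), camera with an estimated correlation (adjusted p = 0.0189 with an estimated correlation) and fry (adjusted p = 0.000164). Its score difference was 1.16, with no overlap between the 5 and 6 libraries (exact permutation p = 0.00216, adjusted p = 0.0801). That exact p is the smallest possible here, so 1 list alone could not pass after adjustment. In the circadian list 1 member passed higher and 9 lower adjusted over the list alone (13 of 18 lower, camera adjusted p = 0.00530; adjusted p = 0.252 with an estimated correlation). Endothelial markers were higher in 11 of 12 cases, 3 of them passing adjusted over the list alone (adjusted p = 3.93e-06; adjusted p = 0.307 with an estimated correlation). Hypertrophy genes were higher in 12 of 13 cases (median 0.55, adjusted p = 1.52e-05; adjusted p = 0.665 with an estimated correlation). Also higher were cell cycle (25 of 27, 1.21e-05), matrix (31 of 36, 2.59e-05), activated fibroblast (9 of 10, 0.0185) and antioxidant genes (15 of 20, 0.0393). Lower were calcium handling (18 of 22, 0.00301), immediate early (18 of 19, 0.00530), sarcomere (16 of 19, 0.00687) and cardiomyocyte genes (12 of 12, 0.0108). Of these lists none passed with an estimated correlation (adjusted p = 0.746, 0.866, 0.866, 0.665, 0.783, 0.866, 0.783 and 0.783 in that order). Without PDE9A inhibitor libraries 1 and 4 the immediate early (adjusted p = 0.547) and antioxidant lists (0.123) no longer passed; with the Rn45s share as a covariate the antioxidant list did not pass (0.0818) but the immediate early list did (0.0468). Without these libraries oxidative phosphorylation (2.93e-05), the tricarboxylic acid cycle (0.000854) and PGC-1, PPAR and ERR regulators (0.0432) passed downward, and macrophage markers (0.0346) and interferon-stimulated genes (0.00579, downward with all libraries) upward. With the Rn45s share as a covariate the first 3 passed too (0.00246, 0.0125 and 0.0412), but macrophage markers (0.0809) and interferon-stimulated genes (0.956) did not. PDE9A inhibitor libraries 1 and 4 had their group's highest macrophage and interferon scores. Leaving them out thus moves both lists upward whatever the drugs did. In oxidative phosphorylation they scored 9.165 and 8.896 (others of the group 8.894 to 9.518). Their tricarboxylic acid cycle scores were 9.175 and 8.851 (others 8.926 to 9.538), and their regulator scores 6.617 and 6.293 (others 6.371 to 6.79). Leaving out these libraries can thus move these 3 lists downward whatever the drugs did. The Rn45s share was highest in the same libraries, so that covariate is no separate check. Adjusted over the list alone, 2 hypertrophy genes and 1 each of the calcineurin, antioxidant and skeletal muscle lists were higher, and 1 each of the calcium handling and sarcomere lists lower. Nppa differed by 0.61 (SE 0.69), Nppb by 0.81 (SE 0.35), Acta1 by 0.78 (SE 0.56), Postn by 0.69 (SE 0.62), Myh7 by 0.07 (SE 0.71) and Col1a1 by -0.10 (SE 0.52) on the log2 scale, none called. Atp2a2 differed by -0.16 (SE 0.17), Myh6 by -0.33 (SE 0.18), Pde9a by 0.48 (SE 0.26), Pde5a by 0.05 (SE 0.10), Prkg1 by -0.07 (SE 0.08) and Npr1 by 0.11 (SE 0.10), none called. With standard errors of this size the data do not show that the drugs act alike on them. Camera called 12 lists, 7 upward and 5 downward, and 1472 genes had an unadjusted p under 0.05 against 707 expected by chance. Here too 707 is only a mean, from which genes that vary together can take the number far. DESeq2 called 35 genes. Cd79b was called with each library left out, where the count ran from 1 to 8 (8 without PDE5A inhibitor library 1, and 2 without PDE5A inhibitor library 2 or PDE9A inhibitor library 1 or 3). It was called with the ear tag series as a term too. It was not called with limma-voom and quality weights, in a model of the 2 groups alone or with a replicate block (log2 fold changes 1.47, 1.41 and 1.34).

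**Figure D4:**
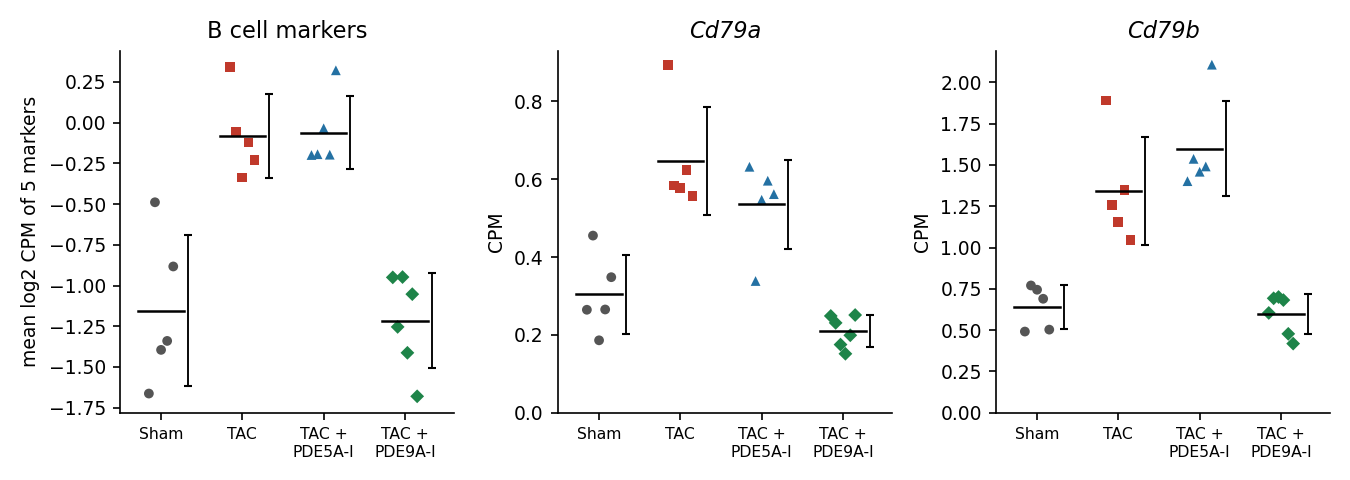
B cell marker score (mean log2 CPM of 5 markers) and CPM of Cd79a and Cd79b per library, with a symbol per group, the group mean as a horizontal line and its SD as the bar beside it. The PDE9A inhibitor libraries have scores from -1.68 to -0.948, below all TAC (-0.337 to 0.340) and PDE5A inhibitor libraries (-0.199 to 0.321) and overlapping the sham libraries (-1.66 to -0.489).

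Each inhibitor group was also compared with sham. The naming rule covers the first 4 comparisons, so the genes named here lie outside it. With the PDE5A inhibitor 2066 genes differed from sham, 963 higher and 1103 lower, and with the PDE9A inhibitor 540, 307 higher and 233 lower, against 3558 in TAC alone. In the PDE5A inhibitor group Nppa (log2 fold change 3.13, SE 0.78), Myh7 (3.79, SE 0.83), Postn (3.04, SE 0.70) and Comp (4.16, SE 0.91) rose, and Atp2a2 fell (-0.60, SE 0.18). In the PDE9A inhibitor group Myh7 (3.72, SE 0.82) and Comp (4.01, SE 0.89) rose, while Nppa (2.52, SE 0.74, adjusted p = 0.0576), Postn (2.35, SE 0.66, adjusted p = 0.0501) and Atp2a2 (-0.44, SE 0.17, adjusted p = 0.110) did not pass. Matrix genes rose in 29 of 36 cases with the PDE5A inhibitor and 12 of 36 with the PDE9A inhibitor, and oxidative phosphorylation genes fell in 16 and 0 of 33. Adjusted over the list alone the numbers were 36 and 31, and 31 and 33. Of the genes called in TAC against sham, 783 and 877 were also called higher and lower with the PDE5A inhibitor, and 272 and 199 with the PDE9A inhibitor, and none was called the opposite way. These comparisons share the sham libraries, and simulated data sets with unchanged inhibitor groups gave a mean of 3117 and 3275 shared calls. On log2 CPM the observed numbers were 1640 and 320, against a 95% range of 1002 to 5329 and 1438 to 5867 in the resampled data sets, of which 10 and 0 of 100 had as few. Genes that rose in TAC had a median log2 fold change against sham of 0.63 in TAC, 0.49 with the PDE5A inhibitor and 0.40 with the PDE9A inhibitor. Those that fell had -0.43, -0.35 and -0.27. These genes were chosen by their change in the same TAC libraries, so smaller medians arise in the other groups with no drug effect. No such value was simulated for the medians. The number of calls for these groups rested on single libraries and on the model. For the PDE5A inhibitor it was 276 with the ear tag series as a term, and 870, 1205, 1127, 1020, 950, 580 and 1058 without sham libraries 1, 2, 3 or 4 or inhibitor libraries 3, 4 or 5. For the PDE9A inhibitor it was 6 with the ear tag series as a term and 18 without libraries 1 and 4. It was 73, 44, 21 and 88 without sham libraries 1, 2, 3 and 4, 162, 29 and 41 without inhibitor libraries 1, 3 and 4, and 1340, 893 and 1814 without inhibitor libraries 2, 5 and 6.

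Whether the inhibitors moved TAC genes back toward sham was measured as the share of the 3558 TAC genes whose inhibitor against TAC change had the opposite sign. It was 82.9% with the PDE5A inhibitor and 92.8% with the PDE9A inhibitor. Cd79a was the only gene called in TAC against sham (log2 fold change 1.08, SE 0.25) and called the other way by an inhibitor. Because the TAC libraries enter both comparisons, a share above 50% arises with no drug effect: simulated unchanged groups gave a mean of 62.4% (highest 63.7%) and 62.8% (highest 63.8%). Resampling whole libraries, which keeps the correlation between genes, widened this range to 23.4 to 94.9% and 18.1 to 93.7% (95% of 100 data sets, on log2 CPM), and shares as high as observed on that scale (82.6 and 94.1%) came up in 30 of 100 data sets for the PDE5A inhibitor and 2 of 100 for the PDE9A inhibitor. With the TAC libraries split so that none was shared, the mean share over 20 splits was 69.1% (23.1 to 100%, above 50% in 16) and 82.9% (40.9 to 100%, above 50% in 19). The TAC genes that these shares rest on numbered 1 to 5073 per split, and the shares of 100% came from 2 splits with 1 gene each. The covariance of the fold changes was -0.0624 and -0.107, against simulated means of -0.0255 and -0.0254. The jackknife standard errors of the shares were 18.8 and 11.8 percentage points. The fold changes of the 2 inhibitors against TAC correlated across genes with Pearson r = 0.469 and Spearman rho = 0.479, where genes are not independent replicates. Simulated unchanged groups sharing the TAC libraries gave 0.528 and 0.480. The covariance was 0.0301 against 0.0262 simulated, and with split TAC libraries the mean r was 0.0497 over 20 splits, from -0.406 to 0.278.

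**Figure D5:**
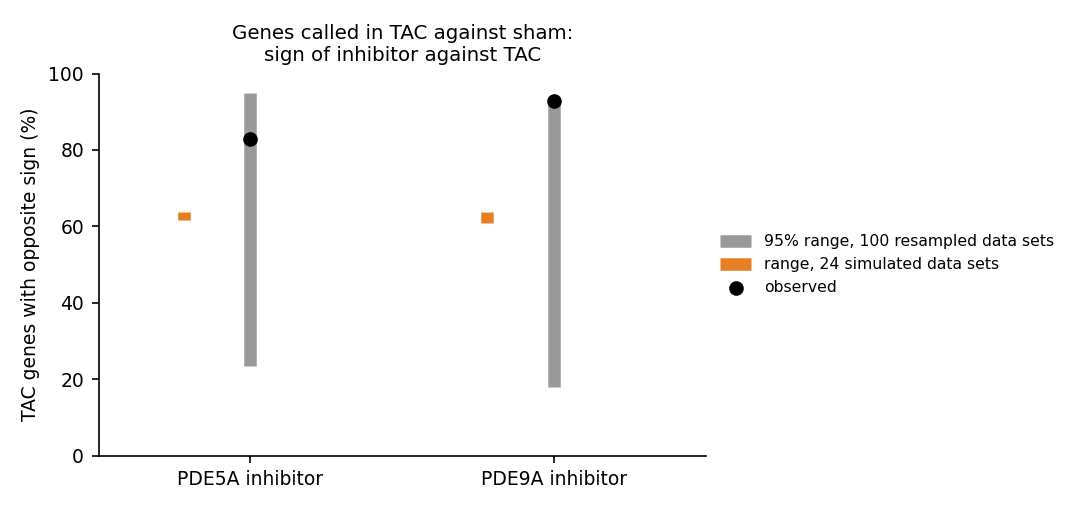
Share of the 3558 genes called in TAC against sham (percent, y axis) whose inhibitor against TAC change has the opposite sign, for each inhibitor. The dots are the observed 82.9% and 92.8%, and the orange bars the range of 24 simulated data sets with unchanged inhibitor groups. The grey bars are the 95% range of 100 resampled data sets, which reaches 94.9% and 93.7%. The grey bars were computed on log2 CPM and the dots were not. On log2 CPM the observed shares, not drawn, were 82.6% and 94.1%, the second above its grey bar.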

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

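The tests that weigh blood, lymphoid tissue, depth, the Rn45s-rich libraries, the ear tag series and the shared TAC libraries, and the regroupings of the libraries for TAC against sham, were chosen after the results were seen; the other regroupings were not.

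B cell markers set the PDE9A inhibitor libraries apart from TAC and the PDE5A inhibitor, though not from sham (scores of -1.68 to -0.948, against -1.66 to -0.489): the inhibitor groups differed by 1.41 (log2) in Cd79b and by 1.16 in the marker score. The Cd79b call (adjusted p = 0.00591) was lost with limma-voom, in the model of the 2 groups and with the replicate block, at log2 fold changes of 1.47, 1.41 and 1.34. The score did not pass over the 37 lists (adjusted p = 0.0801). Its exact permutation p of 0.00216 was the smallest that the design can give, so 1 list alone could not have passed. Less blood in the libraries would lower erythroid transcripts too, but the erythroid score, inhibitor minus TAC, was 0.62 (exact permutation p = 0.102), and no permutation gave it a difference (lowest -0.96) as low as the -1.14 of the B cells. The score difference against TAC was -1.15 without PDE9A inhibitor libraries 1 and 4, and the difference between the inhibitors was 1.09 with counts thinned to the lowest library total. Within the 3 ear tag series the observed mean difference against TAC was -1.14, with 1 of the groups a single library in each series. Permuting labels within the series gave exact p = 0.0222, the smallest that the 45 arrangements can give. These values argue against those libraries, depth and the series as the whole cause of the score. The Cd79a call against TAC (-1.62, SE 0.25) nevertheless ended without libraries 1 and 4 (-1.60, SE 0.29), with the Rn45s share (-1.57, SE 0.26), with the series as a term (-1.48, SE 0.26) and in 10 of 11 fits without 1 library, where a wider spread at a similar fold or fewer libraries left it short of the threshold. Less lymphoid tissue in the dissected piece cannot be told apart: the T and NK cell score differed by 0.26 (exact permutation p = 0.307), on markers with a median of only 10 counts, and fewer B cells in the ventricle under PDE9A inhibition stays an untested hypothesis.

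On the genes changed by TAC, both inhibitor groups lay between TAC and sham. Choosing the genes by the TAC libraries favours this position with no drug effect. For the PDE5A inhibitor 30 of 100 resampled data sets with unchanged groups had an opposite-sign share as high, so the shared TAC libraries may produce the pattern. For the PDE9A inhibitor 2 of 100 resampled data sets did, but 12 of 100 regroupings also gave a share as high, so the shared libraries and a drug effect cannot be told apart. The severity of the constriction in each animal is not given in the sources used here, and a difference in it between the groups was not tested and stays open.

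Groupings of the same libraries other than the real one were tried, 100 per result with the real one included. Chance can be excluded for the 3558 genes of TAC against sham (1 of 100 as large, highest other 0) and the 2066 of the PDE5A inhibitor against sham (1 of 100, highest other 1). The 540 of the PDE9A inhibitor against sham were reached by 2 of 100, but another grouping gave more (617). Their number was 17 in the model of the 2 groups, 6 with the ear tag series, 15 with the Rn45s share and 18 without libraries 1 and 4. Chance is therefore not firmly excluded for them. Regrouping weighs chance only: the share of an ear tag series differed from sham by up to 60 and 66.7 percentage points in the PDE5A and PDE9A inhibitor groups. The 2 of the PDE5A inhibitor against TAC were reached by 4 of 100 (highest other 7). This count makes no allowance for the number of results tried, so chance is not firmly excluded for them. At an unadjusted p under 0.05 there were 731 genes against 707 expected, and limma-voom and the model of the 2 groups called 0. The count of 2 fell to 0 without TAC library 2, 3, 4 or 5 or PDE5A inhibitor library 3, 4 or 5, and to 1 without TAC library 1 or PDE5A inhibitor library 2. Chance cannot be excluded for the number of genes in PDE9A inhibitor against TAC (1 gene, 6 of 100, highest other 633) or between the inhibitors (1 gene, 16 of 100, highest other 1664). Nor can it for the opposite-sign shares of 82.9% (17 of 100, highest other 96.8%) and 92.8% (12 of 100, highest other 97.2%) or for the correlation of 0.469 (66 of 100, highest other 0.883). The number of lists past camera with the preset correlation was reached by other groupings in every comparison tried, so chance cannot be excluded for it: 15 lists in TAC against sham (30 of 100, highest other 22), 11 in PDE5A inhibitor against TAC (46 of 100, highest other 18), 12 in PDE9A inhibitor against TAC (50 of 100, highest other 21) and 12 between the inhibitors (48 of 100, highest other 21). Groupings with several times the real number of calls (633, 1664 and 7, against 1, 1 and 2) point to a structure of the samples. In them the groups lay 32.0, 33.7 and 26.5 apart on the first component, against -21.9, 12.6 and -9.30 in the real ones. The largest gap in the share of an ear tag series was 23.3, 26.7 and 20%, against 46.7, 43.3 and 40%. Other regroupings of the PDE9A inhibitor and TAC libraries, 32.2 and 32.7 apart, gave 0 and 1 calls. On the second component these lay 12.2 and 2.99 apart, and the grouping with 633 calls -12.4. Regroupings -21.8 and -25.9 apart on the second component gave 327 and 0 calls, so what this structure is stays open.

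Single libraries stood far from the others of their group in 34 of 528 groups of values tested, where chance flags about 1 in 20 groups. In total counts (M) these were sham library 4 (41.0), TAC library 2 (22.7) and PDE5A inhibitor library 3 (26.7), and in the Rn45s share PDE5A inhibitor library 5 (0.2277%). In list scores they were PDE9A inhibitor library 4 for sarcomere genes (11.58), sham library 2 for immediate early genes (5.486, nearest other 2.695), sham library 5 for cell cycle genes (2.309), PDE5A inhibitor library 2 for fibroblast (6.375) and lymphatic markers (3.542), TAC library 2 (4.375) and PDE5A inhibitor library 4 (5.544) for smooth muscle markers, and sham library 4 for pericyte markers (6.207). In CPM, PDE9A inhibitor library 6 was apart for Cenpf (96.45), Aqp4 (8.247), Rp1 (1.423), Rxra (104.4) and Prkg1 (36.46); it is also the library with the lowest first component score among the treated. PDE9A inhibitor library 3 was apart for Nppa (3090) and Gdf15 (16, nearest other 3.714), library 1 for Ifit3 (64.51), library 2 for Spen (28.22) and library 4 for Cx3cl1 (36.65). PDE5A inhibitor library 4 was apart for Nppa (3748, nearest other 1192), library 2 for Hsp90b1 (337.9) and Cd79a (0.3386), and library 5 for Cd79b (2.107). TAC library 4 was apart for Furin (76.67) and Ifit3 (37.12), library 2 for Retnla (1.347) and library 1 for Cd79a (0.8932). Sham library 5 was apart for Cycs (989.6) and Tll2 (1.82), library 3 for Rxra (77.83) and library 4 for Sh2b1 (39.9).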

How the results depend on the processing

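The fits without PDE9A inhibitor libraries 1 and 4, those with the Rn45s share as a covariate and the settings of the B cell score were chosen after the data were seen. No named gene changed direction under an alternative where it was called in the main fit or in that alternative. Changes of direction in genes called in neither were not counted. With the TAC libraries split between the comparisons, the opposite-sign share stayed above 50% in 16 and 19 of 20 splits (lowest 23.1 and 40.9%; 1 to 5073 TAC genes per split, 1 gene in 2 of them), and the correlation above 0 in 15 of 20 (lowest -0.406).

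In TAC against sham the count of 3558 genes stayed within 1.5 times under every alternative run except limma-voom with quality weights (6135), and except without TAC library 3 (2019) or 4 (1781) among the left-out libraries (1781 to 4440). Of 88 named genes called, 88 were called with DESeq2, RLE and limma-voom, and 78 with the ear tag series or the Rn45s share as a term. The opposite-sign shares stayed at 72.6 to 90.0% and 85.4 to 96.1%, and the correlation at 0.370 to 0.629, without each library in turn.

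For the PDE5A inhibitor against TAC (2 genes) DESeq2 called 8, limma-voom and the model of the 2 groups 0, the replicate block and the ear tag series 1, and left-out libraries 0 to 2. For the PDE9A inhibitor against TAC (1 gene) DESeq2 called 33, left-out libraries 0 to 46, and no filter, the 1 CPM filter, limma-voom, the model of the 2 groups, the replicate block, the ear tag series, the Rn45s share and the fit without libraries 1 and 4 each called 0. The 1 CPM filter took out Cd79a, the gene of the main fit, before testing, as it reached 1 CPM in no library (highest 0.8932). Between the inhibitors (1 gene) DESeq2 called 35, limma-voom, the model of the 2 groups and the replicate block 0, the fit without libraries 1 and 4 called 2, and left-out libraries 1 to 8. In edgeR 731, 2061 and 1472 genes had an unadjusted p under 0.05.

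For the PDE5A inhibitor against sham (2066) limma-voom called 4308, the model of the 2 groups 3440, the ear tag series 276, the Rn45s share 1137 and left-out libraries 580 to 2274. For the PDE9A inhibitor against sham (540) no filter called 329, DESeq2 1550, limma-voom 351, the model of the 2 groups 17, the replicate block 2241, the ear tag series 6, the fit without libraries 1 and 4 called 18, the Rn45s share 15 and left-out libraries 21 to 1814. Of the 6 PDE9A inhibitor libraries 4 belong to an ear tag series without a sham library, so that term leaves fewer libraries to compare within a series. With an estimated correlation camera called 0, 0, 0 and 1 lists in the first 4 comparisons, and fry 13, 0, 1 and 1. The number of lists was 15, 11, 16 and 15 without PDE9A inhibitor libraries 1 and 4, and 15, 12, 14 and 14 with the Rn45s share. The B cell score differences stayed at -1.28 to -1.08 and 1.03 to 1.26 without each marker. Beyond fewer libraries where one is left out, the cause was not tested. The alternative for the mitochondrial genome could not be run, as the table holds none of its genes. Total counts of 22.7 to 41.0 M leave markers such as Cd79a near 0.2 CPM with a few counts per library, and the limits cover counting error only.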

Other observations

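These lists were tested with the others, but their members named here were chosen after their values were seen. In TAC against sham 4 of 7 Schwann and neural markers fell (among them Sox10 -1.60, Gfra3 -1.77 and Kcna1 -1.68 on the log2 scale; list adjusted p = 0.0700). Of the other cell types, 3 of 6 lymphatic markers rose and 1 fell (adjusted p = 0.180), 2 of 8 smooth muscle markers rose (adjusted p = 0.556) and 1 of 8 pericyte markers rose and 2 fell (adjusted p = 0.346). Of macrophage markers 2 of 13 rose and 1 fell (adjusted p = 0.302), 1 of 4 atrial markers rose and 1 fell (adjusted p = 0.994), 1 of 3 brown adipocyte markers rose and 1 fell (adjusted p = 0.796) and 1 of 3 skeletal muscle markers fell (adjusted p = 0.753). No endothelial (12, adjusted p = 0.878), endocardial (6, adjusted p = 0.282), T and NK cell (4, adjusted p = 0.435), neutrophil (4, adjusted p = 0.461) or erythroid marker (8, adjusted p = 0.0251; adjusted p = 0.618 with an estimated correlation) was called by edgeR, though 5 of 8 erythroid markers were lower adjusted over the list alone.

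PDE9A inhibitor libraries 1 and 4, apart on the second principal component, had inflammation scores of 3.342 and 3.322 (others of the group 1.888 to 2.652), interferon scores of 4.435 and 3.859 (others 2.941 to 3.575) and immediate early scores of 5.165 and 4.163 (others 2.506 to 4.084). They were singled out after their values were seen, and no explanation was tested.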
